A study of Mus musculus with 2 samples.

How the data were processed

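The deposited counts are raw UMI counts per gene and barcode from 10x Chromium 3' v2 libraries, which per the file headers came from Cell Ranger 3.0.0; the authors name Cell Ranger, Seurat 2 and 3, and the builds GRCm38 and mm10. The score in the authors' deposited gene table is an average log fold change of each cluster, whose log base and input values are not given in the sources used here, so it was not used to rank genes. The p-value of that table, with its adjusted form, was computed by the authors across cells, by a test not given in the sources used here; the table lists the genes of each cluster by rising p-value, and the leading 20 in that order were matched to the epithelial clusters. The plan had assumed that this table compares knockout with control, but it compares clusters. Per the labels, each group is 1 library from embryonic day 18.5; both were digested for 20 min, resuspended in 500 µL (control) and 250 µL (knockout), and loaded at 17.4 µL for a target of 10000 cells.

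The samples, comparisons, gene lists, marker genes, rule for named genes and 25 alternatives were fixed before the data were examined; 8 alternatives and the threshold for cells with few UMIs were chosen after seeing the data. Barcodes with under 500 detected genes (1290 control, 1465 knockout) or over 10% mitochondrial UMIs (63 and 57) were left out, and 22 and 24 doublets called by Scrublet in each library were removed. Counts were scaled to 10000 per cell and logged. The 2000 most variable genes, without digestive enzyme, hormone, haemoglobin, mitochondrial, ribosomal protein and sex-linked genes, were scaled, clipped at 10 and reduced to 30 principal components. Cells were joined to 15 neighbours, weighted by shared neighbours and clustered with Leiden at resolution 1, which gave 22 clusters. A cluster was named where at least 3 markers of 1 of 23 classes were among its 50 leading genes and its 10 leading genes did not go against the name. A cluster whose median UMI number was under 1/3 of the library's was kept without a name.

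UMIs were summed per library and class, in classes with at least 50 cells in both libraries, and divided by the class total. A fold against no UMIs uses a floor of 3 counts and is given as "at least". Named genes had at least 100 UMIs in the class and were the 12 with the largest and the 12 with the smallest ratio by the interval bound nearest 1, or 5 each way in mesenchymal-like and endothelial-like cells. Left out of that ranking were haemoglobin, mitochondrial, ribosomal protein and 6 sex-linked genes (Xist, Tsix and 4 Y-linked genes; other genes of the sex chromosomes stayed in), gene models without a symbol, and genes that another class of the same library had at over 5 times the level. In epithelial classes, genes whose mesenchymal log2 ratio had the same sign and at least 50% of the size were left out too. Of each list, the 2 members with most UMIs and the 2 furthest from a ratio of 1 could also be named; genes named within acinar-like clusters were picked after their values were seen. For 22 gene lists with 454 members, of which 9 are not in the files, the median log2 ratio of members with at least 20 UMIs was set against 10000 random lists matched on expression in 20 bins, and its range comes from 200 Poisson resamplings. No test across animals was run.

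The alternatives varied the filters, doublet removal, clustering, totals, depth and free RNA. In a self-test on simulated counts with 200 altered genes per class, all 24 named genes of each epithelial class were altered genes. The true ratio of unaltered genes lay inside the interval for 96.1% (acinar), 95.3% (ductal) and 95.8% (endocrine). These counts held Poisson error only, without free RNA or differences in makeup, and the naming ran without the filters on other classes. The self-test therefore checks the calculation and not those filters. Versions were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Reads were not analysed here. Some genes that the rule names are left out of the text because they are withheld for evaluation.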

Results

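Transcripts were counted in single cells of mouse pancreas at embryonic day 18.5, in 1 library labelled control and 1 labelled knockout, which the series calls Dpy30∆P. The control library held 3986 barcodes and 25398522 UMIs (unique molecular identifiers, which count captured transcripts), and the knockout library held 4779 barcodes and 33048640 UMIs. After filtering, 2611 and 3233 cells were kept, with medians of 6831 and 6631 UMIs and of 2233 and 2138 detected genes. With 1 library per group, no difference given here has a replicate check. All intervals are 95% intervals that cover counting error only: Clopper-Pearson for shares, Katz for ratios of shares, exact Poisson for UMI sums and exact conditional binomial for ratios of counts scaled to the total UMIs of the class (CPM). The libraries also differed in sex. Xist, the transcript that coats the inactive X chromosome, had 1 UMI in the control library and 48052 in the knockout library, and Ddx3y, a gene of the Y chromosome, had 1624 and 0, so sex and genotype cannot be separated.

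The opening question was whether the gene named in the design was lower in the library labelled knockout. It was not. Dpy30 (ENSMUSG00000024067) encodes a subunit shared by the TrxG complexes, which methylate histone tails at active genes. Its tags stood at 158 CPM in endocrine-like cells of the control library and at 291 CPM in those of the knockout library, a ratio of 1.84 (1.64 to 2.06). Of the 598 knockout UMIs, 284 came from an unnamed endocrine sub-cluster of 86 knockout and 2 control cells, at 447 CPM, and progenitor-like cells lay the other way, with 171 and 133 CPM and a ratio of 0.781 (0.566 to 1.08). The ratio was 1.52 (1.25 to 1.85) in acinar-like cells and 1.20 (1.09 to 1.33) in ductal-like cells. Outside the epithelium, mesenchymal-like cells had 68.3 and 74.7 CPM, with a ratio of 1.09 (0.957 to 1.25), and endothelial-like cells had 106 and 102 CPM, with a ratio of 0.969 (0.753 to 1.24). The median log2 ratio of all genes also differed by class. It was 0.24 in endocrine-like, 0.19 in acinar-like, 0.03 in ductal-like, 0.00 in mesenchymal-like and −0.01 in endothelial-like cells. The log2 ratio of Dpy30 in endocrine-like cells was 0.88. After thinning of every cell to 2000 UMIs, 28.5% of control and 44.5% of knockout endocrine-like cells held a Dpy30 UMI, against 10.1% and 12.8% of mesenchymal-like cells. The full median depths were 9301.5 and 7325 UMIs in the endocrine-like and 5632 and 5524 UMIs in the mesenchymal-like cells. Dpy30 lies on the minus strand of chromosome 17 (GRCm38), and its last exon, exon 5, spans 74299656 to 74299824. Tags of a 3' library come from near the 3' end of transcripts. The last exon is 169 bases long, so tags may also lie upstream of it. Reads were not analysed, and the labels do not state which part was deleted. The tags therefore check neither the deletion nor the library labels.

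**Figure D1:**
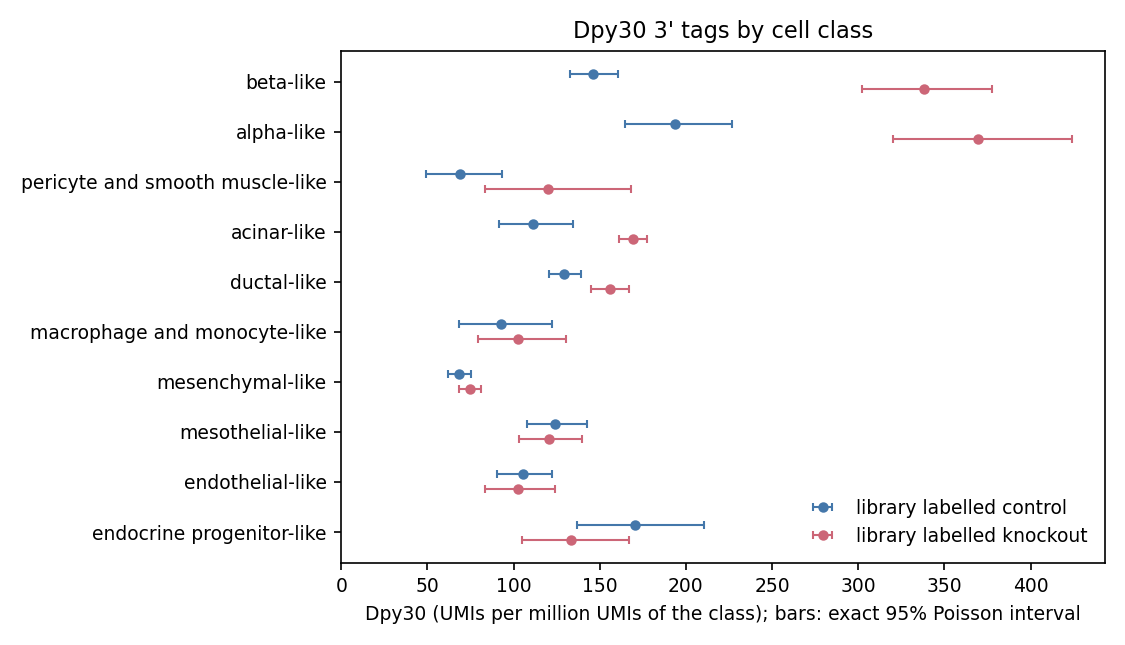
Dpy30 level (CPM, horizontal axis) in each cell class (vertical axis) with at least 40 kept cells in both libraries; points are the library sums and bars their exact 95% Poisson intervals. In beta-like cells the control point lies at 146 CPM and the knockout point at 338 CPM. This class is of mixed makeup. Of its 217 control and 95 knockout cells, 156 and 31 fell in the beta-like sub-clusters. Within the beta-like sub-clusters of the whole family the ratio was 2.06 (1.66 to 2.53).

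A further question was how the makeup of the pancreas differed. Acinar-like cells, which make digestive enzymes, took a larger part of the epithelium in the library labelled knockout, and ductal-like and endocrine-like cells took smaller parts. Acinar-like cells were 11.1% of epithelial cells in the control library (9.17% to 13.2%, 109 of 985 cells) and 55.0% in the knockout library (52.3% to 57.6%, 760 of 1382), a ratio of 4.97 (4.14 to 5.97). Ductal-like cells were 52.0% (48.8% to 55.1%) and 28.4% (26.1% to 30.9%), a ratio of 0.547 (0.494 to 0.606). The endocrine family, which is progenitor-like, alpha-like and beta-like cells together, was 37.0% (33.9% to 40.1%) and 16.6% (14.6% to 18.6%), a ratio of 0.448 (0.388 to 0.518). Over all kept cells, acinar-like cells were 4.17% and 23.5%, ductal-like cells 19.6% and 12.2%, and the endocrine family 13.9% and 7.08%.

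Within the endocrine family, beta-like cells, the insulin producers, were 59.6% in the control library and 41.5% in the knockout library, a ratio of 0.696 (0.584 to 0.829); their cluster also held cells rich in somatostatin (Sst). Alpha-like cells, which make glucagon, were 26.4% and 30.6%, a ratio of 1.16 (0.894 to 1.50). Cells led by Neurog3, the factor that commits progenitors to the endocrine lineage, were 14.0% and 27.9%, a ratio of 1.99 (1.44 to 2.77), but of the whole epithelium they were 5.18% and 4.63% (ratio 0.894, 0.625 to 1.28). When each library was clustered alone, the beta-like ratio was 1.00, but no knockout cluster was then named alpha-like. That setting gave 95 alpha-like, 187 beta-like and 49 progenitor-like control cells, and 0, 186 and 143 knockout cells. Its ratio therefore rests on how clusters were named and does not show an equal beta-like share. The shares from the joint clustering count cells of the unnamed sub-cluster. In a sub-clustering of the family chosen after seeing the data, which sets those cells apart, beta-like cells were 43.7% and 13.5% (ratio 0.310, 0.219 to 0.439) and alpha-like cells 24.7% and 7.42% (0.30, 0.184 to 0.491). Outside the epithelium, endothelial-like cells were 6.86% and 3.65% of kept cells, a ratio of 0.532 (0.424 to 0.668), and pericyte-like and smooth-muscle-like cells were 3.49% and 1.39%, a ratio of 0.399 (0.281 to 0.569). Mesenchymal-like cells were 36.7% and 38.0%, and macrophage-like cells 3.33% and 3.34%. A cluster with few UMIs and acinar transcripts was left unnamed, and its 47 control cells (1.80%) and 93 knockout cells (2.88%) count as kept cells only.

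**Figure D2:**
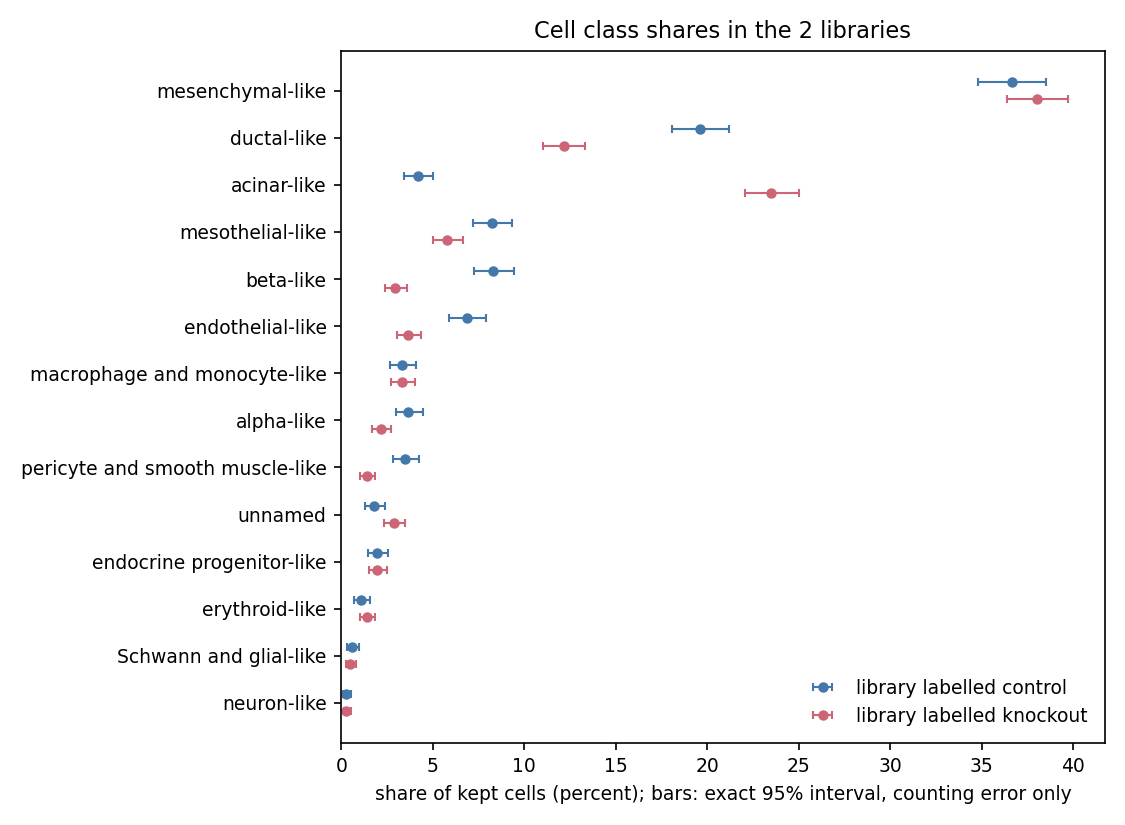
Share of kept cells (percent, horizontal axis) in each class, with the unnamed cluster (vertical axis), for the library labelled control and the library labelled knockout; bars are exact 95% Clopper-Pearson intervals. Acinar-like cells lie at 4.17% in the control library and 23.5% in the knockout library.

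Acinar-like cells were compared next. They fell into clusters 4, 7 and 16, and cluster 4 was held almost wholly by the library labelled knockout, with 445 knockout cells and 1 control cell; the 445 were 58.6% (55.0% to 62.1%) of that library's acinar-like cells. Clusters 7 and 16 were shared, with 91 and 252, and 17 and 63, control and knockout cells. Digestive enzymes had been left out of the clustering, yet the knockout cells of cluster 4 carried a different mix of them from the knockout cells of clusters 7 and 16. Higher in cluster 4 were Pla2g1b, a phospholipase (20.5-fold, 15.4 to 28.0), Reg1, a secreted lectin (14.7-fold, 14.0 to 15.4), Ctrl, a chymotrypsin-like protease (8.28-fold), Prss3, a trypsinogen (6.24-fold), and Cela1, an elastase (4.32-fold). Lower in cluster 4 were the elastases Cela2a (9.15-fold) and Cela3b (8.83-fold), Clps, the cofactor of pancreatic lipase (7.61-fold), Pnliprp1, a lipase-related protein (6.91-fold), and the carboxypeptidases Cpb1 (5.93-fold) and Cpa1 (3.57-fold). Ptf1a and Rbpjl, partners in the factor that drives enzyme genes, were higher in cluster 4 by 1.67-fold (1.51 to 1.85) and 1.53-fold (1.43 to 1.62).

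**Figure D3:**
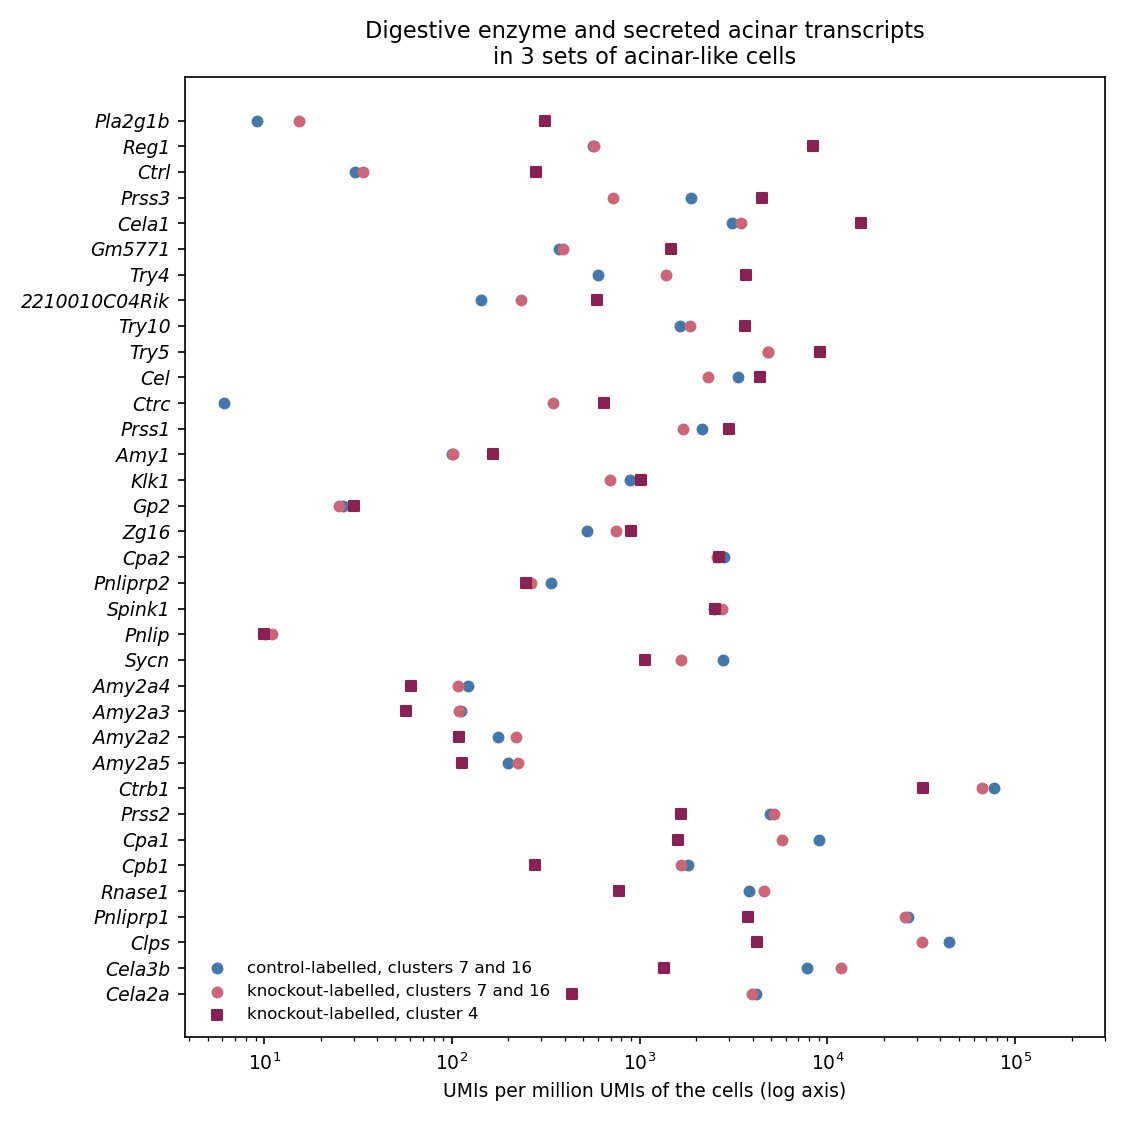
Level of each digestive enzyme or secreted acinar transcript (vertical axis) in CPM (horizontal log axis) for control cells of clusters 7 and 16, knockout cells of clusters 7 and 16, and knockout cells of cluster 4, with 1 point per set of cells and no error bars. Pla2g1b lies at 9.12, 15.3 and 313 CPM in these sets, and Cela2a at 4142, 3977 and 435 CPM.

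Over the whole acinar-like class, the genes named as furthest higher in the library labelled knockout were led by Ctrc, chymotrypsin C, with 5.98 CPM in the control library and 552 CPM in the knockout library, a ratio of 92.4 (42.4 to 252). Cela3a, an elastase, had 1.99 and 62.7 CPM (31.5, 8.68 to 261), and Pla2g1b had 8.96 and 221 CPM (24.6, 13.0 to 54.0). The secreted lectins Reg3b, Reg3g and Reg3d were among them: Reg3b had no UMI in the control library and 79.0 CPM in the knockout library, at least 26.4-fold higher, Reg3g was at least 19.1-fold higher, and Reg3d was 22.9-fold higher (8.93 to 84.4). The others were Acta1, skeletal actin (at least 14.3-fold), Gstm6, a glutathione transferase (23.5-fold, 6.47 to 195), Klk1b5, a kallikrein (17.5-fold, 5.97 to 85.3), Serpina16 (at least 9.84-fold), Tff3, a trefoil peptide (at least 7.30-fold), and Rbp2, a retinol-binding protein (8.16-fold, 5.32 to 13.2). Many of these were smaller in clusters 7 and 16 alone. There Reg3b and Reg3g had no control UMI and 3.57 and 4.22 CPM in the knockout library, too few to place them higher, and Pla2g1b had a ratio of 1.67 (0.810 to 3.88). Ctrc and Cela3a differed there too, with ratios of 56.6 (25.9 to 154) and 75.7 (20.8 to 627), as did Reg3d (4.16, 1.53 to 15.8), Gstm6 (4.64, 1.17 to 40.1), Rbp2 (1.97, 1.22 to 3.34) and Acta1 (at least 2.67).

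Lower in acinar-like cells of the library labelled knockout were Sostdc1, a secreted BMP and WNT inhibitor, at 107 and 23.4 CPM (4.55-fold, 3.59 to 5.75), Clps (3.42-fold), Cpa1 (3.19-fold), Cckar, the cholecystokinin receptor (2.98-fold), Cela2a (2.67-fold), Cpb1 (2.54-fold) and Pnliprp1 (2.51-fold). The lipid genes Fasn, fatty acid synthase (3.25-fold), Scd2, a fatty acid desaturase (3.04-fold), and Tmem97, a sterol-regulated membrane protein (2.41-fold), were lower as well, as were Snhg18 (3.03-fold) and Nccrp1 (3.93-fold). In clusters 7 and 16 the fold lower was 3.64 for Sostdc1, 4.26 for Nccrp1, 2.07 for Fasn and 1.58 for Cpa1, and between 1.04 and 1.38 for the other 8 genes. Nccrp1 had 30 control UMIs, and its log2 ratio was −1.97 at full depth and 0.17 after thinning.

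Gene lists fixed in advance were read against the median log2 ratio of all measured genes, 0.19 in the acinar-like class and 0.06 in its clusters 7 and 16. Digestive enzymes and secreted acinar proteins had a median of 0.08 (−0.03 to 0.16), with 20 members higher and 16 lower, and Ctrb1, the most abundant, was 1.79-fold lower. That median turned to −0.04 and −0.10 with the scalings that took the shift of all genes to 0.07 and 0.01. Acinar transcription factors had 9 of 10 members higher and a median of 0.23 (0.12 to 0.41), with Ptf1a 1.31-fold (1.12 to 1.53) higher, but the median in clusters 7 and 16 was −0.01. Genes of S phase (median −0.40, 23 of 30 members lower), of G2 and M phase (−0.22, 22 of 32 lower) and of the secretory pathway of the endoplasmic reticulum (−0.25, 25 of 32 lower) were lower over the class but not in clusters 7 and 16, where their medians were 0.13, 0.54 and 0.07. Immediate early and dissociation response genes were higher in both sets, with medians of 0.42 and 0.30; Nr4a1, which responds to cell stimulation, was 3.48-fold (2.34 to 5.41) higher. The p53 response (0.43), with Plk2 2.07-fold higher, and acinar injury genes (0.34), with Nupr1 1.22-fold higher over the class, stood above the shift of all genes, and the unfolded protein response (−0.04) stood below it. In clusters 7 and 16 injury genes (−0.12) and the unfolded protein response (0.19) lay on the other side of the shift, while the p53 response was at 0.30. The control side of this class rests on 109 cells with a median of 6073 UMIs, against 11642 UMIs in the knockout cells.

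In ductal-like cells the median over all genes was 0.03. Genes of duct identity were lower in the library labelled knockout, and genes of DNA replication were higher. Of 28 measured ductal genes 24 were lower, with a median of −0.34 (−0.39 to −0.28), and none of the 10000 expression-matched random lists lay lower. Spp1, a secreted phosphoprotein of ducts, was 1.40-fold lower, Clu, a secreted chaperone, 1.39-fold, and Krt19, a duct keratin, 1.56-fold (274 and 176 CPM). S phase genes were higher in 29 of 30 cases (median 0.30, 0.24 to 0.38), with Ccne1, a cyclin that drives entry into S phase, 3.20-fold (1.73 to 6.23) higher, while G2 and M phase genes had a median of 0.07. Cluster 9, the more deeply sequenced of the 2 ductal clusters, took 27.7% of the class in the control library and 40.5% in the knockout library. The authors' clusters led by the cycling genes Mcm6, Cenpf and Kif20a lay nearest to it, so the S phase and duct differences were not separated from this makeup. Immediate early and dissociation response genes were lower in 18 of 23 cases (median −0.28), with the heat shock gene Hspa1a 7.69-fold lower. The TrxG complex members had 14 of 18 higher (median 0.23), with the demethylase Kdm6a, which is X-linked, at 1.85-fold (1.42 to 2.42) and Rbbp5 at 1.84-fold. Trunk progenitor transcription factors had a median of −0.14, with Sox9 1.10-fold lower. Among Notch and Hippo pathway genes (median 0.09), the Notch targets Hey1 and Nrarp were 3.93-fold and 2.00-fold higher, and Hes1 was 1.30-fold lower.

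Genes named as furthest higher in ductal-like cells of the library labelled knockout were Serpina3a, a serine protease inhibitor (none in the control library and 33.9 CPM, at least 67.1-fold), Krt17, a keratin of stressed and basal epithelia (21.5 and 82.7 CPM, 3.84-fold, 3.14 to 4.72), and the chemokine Cxcl10 (3.63-fold, 2.46 to 5.48). The others were Adamtsl1 (4.53-fold), Ugt2b36, a glucuronosyltransferase (4.42-fold), Vnn1 (2.72-fold), Wfdc18 (2.65-fold), Aldh1b1, an aldehyde dehydrogenase of pancreatic progenitors (2.36-fold), Col2a1 (2.29-fold), Scpep1 (2.27-fold), Hebp1 (2.02-fold) and the linker histone gene Hist1h1b (1.95-fold). Lower were Ass1, of arginine synthesis (81.6 and 35.9 CPM, 2.27-fold, 1.91 to 2.72), Slc2a1, the glucose transporter GLUT1 (80.1 and 41.9 CPM, 1.91-fold, 1.62 to 2.26), Aire, a transcriptional regulator best known from the thymus (2.57-fold), and Pdzk1ip1 (447 and 258 CPM, 1.73-fold). Unc5cl, Cenpv, Vill, Tcirg1, Pdgfd, Selenbp1, Osgin1 and Grcc10 were lower by 1.78-fold to 2.38-fold.

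In endocrine-like cells the median over all genes was 0.24. Genes of mature beta cells and hormones were lower in the library labelled knockout, and endocrine progenitor genes such as Neurog3 were higher over the whole class. Of 16 measured beta cell maturation genes 15 were lower, with a median of −1.04 (−1.15 to −0.87) and no random list below. Slc2a2, the glucose transporter GLUT2, was 4.03-fold lower, Cox6a2, a subunit of cytochrome oxidase, 5.73-fold, and Slc30a8, which loads zinc into insulin granules, 2.42-fold. Hormones had a median of −0.66 with 6 of 9 lower; Ins2 and Ins1 were each 2.49-fold lower and Npy was 2.79-fold lower. Within beta-like sub-clusters Ins1 was 1.17-fold (1.15 to 1.18) and Ins2 1.05-fold (1.04 to 1.06) lower, and Npy had a ratio of 1.00 (0.912 to 1.10). Endocrine secretory and vesicle genes had 20 of 25 lower (median −0.14), with Chga 1.69-fold lower, but with progenitors left out the median was 0.08. The endoplasmic reticulum lists were lower too over the whole class, the unfolded protein response at −0.36 and the secretory pathway at −0.30. Hsp90b1 was 1.60-fold lower. The makeup of the class differed between the libraries. Endocrine progenitor genes had a median of 0.41, with 14 of 20 higher and Neurog3 at 341 and 731 CPM (2.15-fold, 1.99 to 2.31). Without progenitors that median was 0.21, below the 0.25 of all genes, and within progenitor-like cells it was −0.14. Endocrine transcription factors (0.15) stood near the shift of all genes, with Pou3f4, which is X-linked, 2.42-fold higher and Irx1 3.21-fold lower. Over the whole class of differing makeup, S phase genes were lower in 22 of 30 cases (median −0.52). There p53 response genes were higher in 14 of 15 (median 0.48). Immediate early and dissociation response genes were higher in 19 of 24 (median 0.44), but their median was 0.28 without progenitors, near the shift of all genes, and −0.014 within beta-like and −0.46 within alpha-like sub-clusters.

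Genes named as furthest higher in endocrine-like cells of the library labelled knockout were Cartpt, a neuropeptide of immature islet cells (14.7 and 195 CPM, 13.3-fold, 10.2 to 17.6), Cdkn1a, the cell cycle inhibitor p21 (170 and 536 CPM, 3.16-fold, 2.88 to 3.48), Neurod2, a neurogenic transcription factor (4.41-fold, 2.91 to 6.79), Pcp4 (3.79-fold) and Kit, a receptor kinase (3.38-fold). The others were Tff3 (3.43-fold), Crybb1 (3.11-fold), Gap43 (2.73-fold), Abca1, a cholesterol exporter (2.69-fold), Hnf1aos1 (2.66-fold), Hmgn5 (2.54-fold) and Ogt, which attaches N-acetylglucosamine to proteins (2.51-fold); Hmgn5 and Ogt are X-linked. Without progenitors Crybb1 was 1.88-fold (1.04 to 3.32), Tff3 6.21-fold and Neurod2, with no control UMI left, at least 10.1-fold higher. Lower were Nnat, an imprinted gene of beta cells (2857 and 860 CPM, 3.32-fold, 3.16 to 3.49), Prss53 (77.8 and 15.5 CPM, 5.01-fold, 3.48 to 7.44), G6pc2, a glucose-6-phosphatase of islets (179 and 70.5 CPM, 2.54-fold, 2.13 to 3.06), Prlr, the prolactin receptor (3.31-fold), the ion channel gene Trpm5 (3.24-fold) and Ccnd2, a cyclin of beta cell replication (587 and 266 CPM, 2.20-fold). The heat shock genes Hspa1b (5.23-fold) and Hspa1a (2.61-fold), and Lgi2, Tmem215, Aldh5a1 and Fam159b (2.78-fold to 4.84-fold), were lower as well. The class holds fewer beta-like and more progenitor-like cells in the knockout library, and 37.6% of its knockout cells sit in the unnamed sub-cluster, among whose leading genes is Pcp4. Within beta-like sub-clusters Cartpt had 15.3 and 4.67 CPM, a ratio of 0.305 (0.0357 to 1.18). The median of beta cell maturation genes was −0.80 without progenitors and −0.08 (−0.24 to 0.05) within beta-like sub-clusters, which held 159 control and 31 knockout cells. Of these, 48 control cells and 0 knockout cells formed a sub-cluster led by Npy, Ins1, Cox6a2 and G6pc2, so the sub-clusters compared were not the same set in both libraries.

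**Figure D4:**
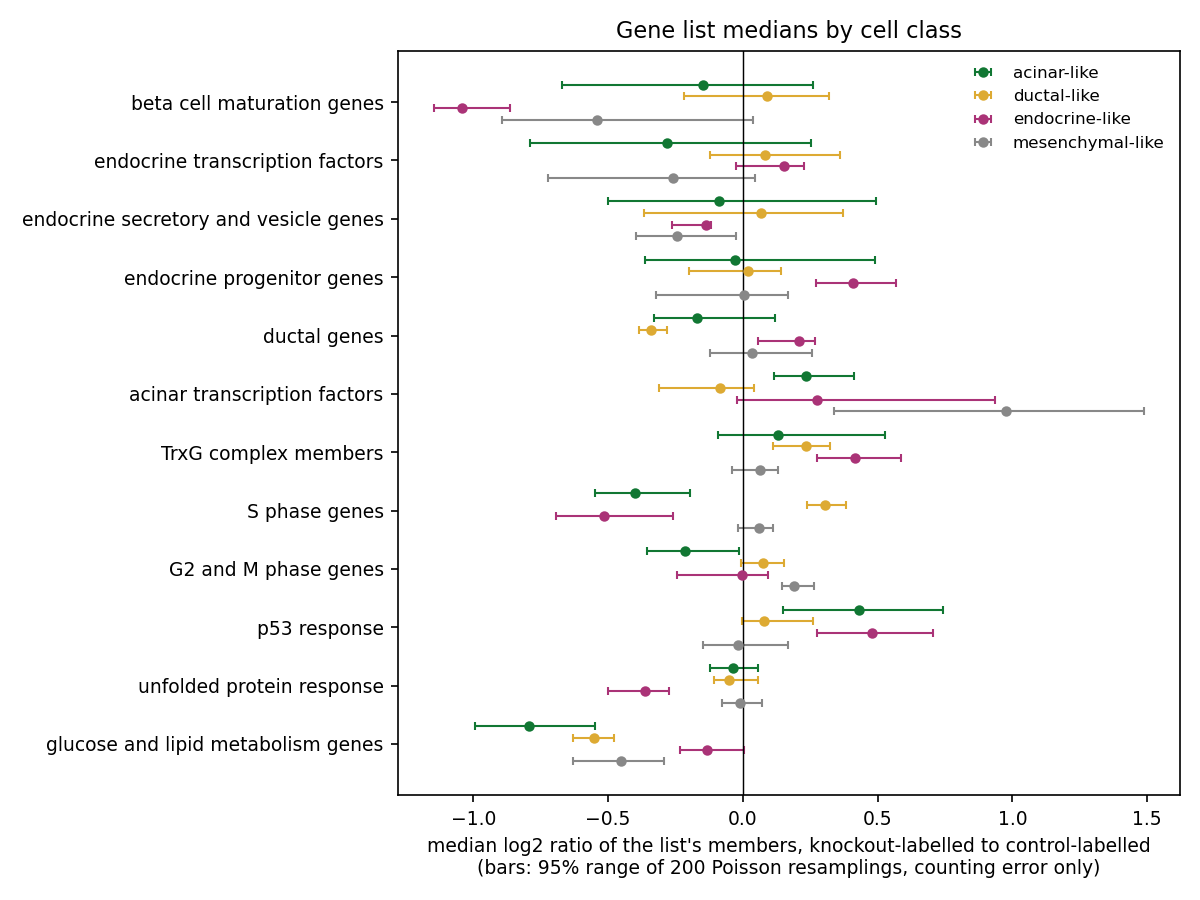
Median log2 ratio of the members of 12 gene lists (knockout-labelled to control-labelled, horizontal axis) in acinar-like, ductal-like, endocrine-like and mesenchymal-like cells; bars are the 95% range of 200 Poisson resamplings of the counts. Beta cell maturation genes lie at −1.04 in endocrine-like cells, and ductal genes at −0.34 in ductal-like cells.

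Free RNA differed between the libraries and moved with the classes. Digestive enzymes took 0.0740% of the UMIs of mesenchymal-like cells in the control library and 0.160% in the knockout library, and hormones took 0.0640% and 0.0129%. In endocrine-like cells the enzyme list accordingly had all 25 measured members higher, with a median of 2.11, and in mesenchymal-like cells 26 of 27, with a median of 1.61. Hormones were lower in acinar-like cells (median −1.92, 8 of 8) and in ductal-like cells (−2.16, 8 of 8), levels at which no expression by these cells can be read.

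The deposited gene table of the authors compares clusters with each other and not knockout with control, so its directions could not be set beside these ratios. It holds 2144 pairs of a gene and a cluster over 14 numbered clusters, and some genes recur. Matched to the epithelial clusters by the leading 20 genes in the order of the table, which is by p-value, the authors' cluster 2 (Bfsp2, Lef1, Gamt) lay nearest to acinar-like cluster 4, clusters 8 (Bfsp2, Lef1, Cd69) and 11 (Cpb1, Spink1, Cela2a) to acinar-like cluster 7, cluster 7 (Ppp1r1a, Nnat) to the beta-like cluster and cluster 9 (Neurog3) to the progenitor-like cluster. The match of cluster 8, which shares leading genes with cluster 2, was weak, with a median log2 fold of 0.023 over the other epithelial clusters.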

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

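All tests of Dpy30 tags were chosen only after the result was seen, as were the tests of free RNA, of every cell type and of sex or stage for the acinar cluster, and of every cell type for the endocrine sub-cluster.

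Xist, which only cells with an inactive X chromosome transcribe, had 48052 UMIs in the library labelled knockout and 1 in the control library, a signal in data outside the main measurement. Female tissue in the knockout library and male tissue in the control library would give these counts, and Kdm5d, a gene of the Y chromosome, had 0 UMIs in the knockout library and 292 in the control library.

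Acinar-like cluster 4 came almost wholly from the library labelled knockout. Enzymes were 11.0% of its UMIs against 0.160% in mesenchymal-like cells, 68.9-fold more, so free RNA at the mesenchymal level does not give its enzymes. Its name already rested on acinar markers, so this value does not test why 1 library holds the cluster. Doublets with mesenchymal-like cells are unlikely, as 10 mesenchymal genes reached 1.51% of their mesenchymal level (other doublets were not tested). Of knockout mesenchymal-like cells, 0% (0 of 1230) sat in a cluster of this kind. Those cells still differed between the libraries, as in genes of sterol synthesis and uptake (median log2 ratio −1.44). A shift of every cell type therefore stays open. With acinar-like cells of at least 2000 UMIs thinned to 2000, 52.1% of knockout cells still sat in clusters with under 5% control cells. Depth therefore does not account for such clusters among these cells. Whether the 52.1% were the cells of cluster 4 was not checked. The unnamed cluster with few UMIs and acinar transcripts, with 47 control cells, did not enter the test, so depth stays open for it. Sex or stage stays open too with 1 library per group, beside a true effect of the deletion.

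Dpy30 tags were higher, not lower, in endocrine-like cells of the library labelled knockout. Totals account for part of it but not all. With hormone, enzyme, haemoglobin and mitochondrial UMIs left out of the totals, the ratio fell from 1.84 to 1.57 (1.40 to 1.75). Free RNA is unlikely, with a ratio of 1.09 in mesenchymal-like cells. Within beta-like sub-clusters, which held 31 knockout cells, the ratio was 2.06 (1.66 to 2.53), so cell types alone do not account for it there. Over the class, makeup may carry part of it, as 284 of the 598 knockout UMIs came from the unnamed sub-cluster. The alpha-like sub-cluster had 186 CPM (156 to 220) in control and 240 CPM (166 to 335) in knockout cells. The delta-like sub-cluster had 217 CPM (176 to 266) and 310 CPM (235 to 401). Both were higher in the knockout library, with overlapping intervals, and overlap does not show equal levels. The progenitor-like sub-cluster had 140 and 113 CPM. Swapped labels would also give the ratio of 1.84, and so might a transcript that keeps its last exon; the tags do not decide between these.

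An endocrine sub-cluster with 86 knockout and 2 control cells held 37.6% of the endocrine-like cells of the library labelled knockout. After thinning to 2000 UMIs, 0% of knockout cells formed a sub-cluster of this kind, and without 7494 genes that other classes have at over 5 times the level the value was again 0%. Depth of the endocrine cells and free RNA from other cells therefore both stay open, and the sub-cluster is not read as a cell state. Both clusterings also gave fewer sub-clusters (6 and 7), so the 0% may reflect lost resolution. The leading genes Hba-a1, Cpa1 and Reg1 do not decide it, as they were left out of the clustering. Nor was its median depth the lowest, at 6910.5 UMIs against 5772 in the delta-like and 6116 in the progenitor-like sub-cluster. Other leading genes of the sub-cluster include Xist and Tsix, which follow sex, and Pou3f4, an X-linked member of the endocrine transcription factor list. The source of these stays open. Whether the libraries differ in every cell type stays open, since the 0% of mesenchymal-like cells in such clusters comes from the main clustering, where endocrine-like cells gave 0% too.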

How the results depend on the processing

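No paired analysis was possible because the groups share replicate number 1 only. The alternatives were 25 listed in advance and 8 chosen after seeing the data. Of the values that answer a comparison, 46 stayed within their interval, 15 moved and 0 were counted as reversed. Of the others 1163 stayed, 248 moved and 19 were counted as reversed. A reversal was counted only where the main interval left out no difference. The median of acinar enzymes, whose interval held 0, therefore counts as moved although its sign turned. Depth limits the control acinar-like cells (109 cells, 1004086 UMIs) and the knockout beta-like sub-clusters (31 cells, 428055 UMIs). Except where said, the cause was not tested.

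The acinar share ratio of 4.97 ranged from 3.06 to 6.05: 6.05 with at least 1000 detected genes, 3.83 (added) with the low-UMI cluster as acinar, and 3.06 (added) without cluster 4. Without cluster 4 the ductal ratio was 0.806, the endocrine ratio 0.661, and the epithelial share of kept cells turned from 1.13 to 0.891, by construction. With each library clustered alone, the ductal ratio was 0.421 and the endocrine ratio 0.677. The beta share of the endocrine family turned from 0.696 to 1.00 there, with no knockout cluster named alpha-like.

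In acinar clusters with at least 10 cells in both libraries (added), these log2 values turned: Serpina16 to −1.23 and Tff3 to −0.23, by construction, since the floor for no control UMIs weighs more in a smaller total; acinar transcription factors to −0.014, S phase to 0.13, G2 and M phase to 0.54, the secretory pathway to 0.072, mitochondrial transcripts to −0.27 and injury genes to −0.12. After thinning, Nccrp1 turned to 0.17.

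With totals free of enzyme, hormone, haemoglobin and mitochondrial UMIs, Dpy30 in endocrine-like cells was 0.65 and beta cell maturation genes −1.28; acinar enzymes turned to −0.044, acinar mitochondrial transcripts to −0.046 and ductal genes in endocrine-like cells to −0.022. With median of ratios the last 4 were −1.30, −0.10, −0.11 and −0.043. Both scalings lowered all genes alike, by construction: the shift of all genes went from 0.19 to 0.068 and 0.0071 in acinar-like and from 0.24 to 0.011 and −0.0098 in endocrine-like cells, so relative to it these values stayed on the same side. Without progenitors (added), Dpy30 was 1.16 and beta cell maturation genes −0.80; ductal genes in endocrine-like cells turned to −0.083 and endocrine secretory genes to 0.0805. With free RNA subtracted, enzymes in ductal-like cells turned from 0.18 to −1.80. With the mean over cells, ductal genes in ductal-like cells were −0.28, and mitochondrial transcripts in endothelial-like cells turned from −0.04 to 0.025.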

Other observations

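The sterol test and the test of how H2-D1 is counted were chosen only after the result was seen.

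In mesenchymal-like cells, whose median over all genes was 0.00, the genes furthest higher in the library labelled knockout were Hddc3 (4.12-fold, 2.93 to 5.94), Crabp1, a retinoic acid binding protein (3.40-fold, 2.91 to 3.98), Erdr1, annotated in the end of the Y chromosome that is shared with the X (2.63-fold), Unc5d (2.50-fold) and Cap1, an actin regulator (2.42-fold). Furthest lower were genes of sterol synthesis and its control, Fdps (3.49-fold, 3.01 to 4.05), Idi1 (3.43-fold), Msmo1 (3.41-fold) and Insig1 (2.90-fold). In endothelial-like cells (median −0.01), Mgp, a matrix protein of vessels (17.3-fold, 9.56 to 34.3), Hebp1 (4.71-fold), the elastic fibre genes Fbln5 (3.66-fold) and Eln (3.30-fold), and Cap1 (2.90-fold) were higher. Lower there were H2-K1 (4.85-fold) and H2-D1 (2.07-fold), which present antigens, Hspa1a (4.80-fold), Igfbp3 (2.61-fold) and Kcne3 (2.41-fold). Hddc3 was also higher in ductal-like cells (4.27-fold, 3.08 to 6.01) and in acinar-like cells (18.5-fold, 3.28 to 733.7, with 1 control UMI).

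Metabolic genes had medians of −0.79 in acinar-like, −0.55 in ductal-like, −0.13 in endocrine-like, −0.45 in mesenchymal-like and −0.23 in endothelial-like cells. The glycolysis members had medians of −0.19 in acinar-like, −0.47 in ductal-like and 0.17 in endocrine-like cells, where 5 of 13 were lower. Among sterol genes, Fdps was 3.92-fold lower in acinar-like cells. Imprinted genes had a median of 0.47 in endothelial-like cells, with 13 of 13 higher, and 0.35 in endocrine-like cells, with 10 of 16 higher and percentile 91.5 of random lists. Igf2 was 4.69-fold higher there, beside Col3a1 (4.22-fold) and Col1a1 (6.29-fold), and a sub-cluster of 12 knockout and 3 control cells was led by these mesenchymal genes. Mitochondrial transcripts had a median of 0.08 in acinar-like cells. TrxG complex members had a median of 0.42 in endocrine-like cells, with Kmt2a 1.47-fold higher, and 0.07 in mesenchymal-like cells. All genes stood at 0.24 in the endocrine-like class, whose makeup differed between the libraries, so this is not read as a rise within a cell type. Sex-linked genes had a median of −4.89 in ductal-like cells, from the Y-linked members.

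The 9 sterol genes had a median of −1.97 in acinar-like, −1.02 in ductal-like, −0.38 in endocrine-like and −1.44 in mesenchymal-like cells. In endothelial-like cells 7 of them were measured, with a median of −0.60 and 6 lower. The mesenchymal value, part of which had been seen before the test was set, shows that the lower level was not limited to the pancreatic epithelium; where it arises was not tested.

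A stretch of chromosome 17 from another strain around Dpy30 was a further hypothesis, for the lower H2-K1 and H2-D1. The 55 genes within 10 Mb of Dpy30 lay at percentile 96.0 of random lists for their median absolute log2 ratio (0.20 against 0.16), in line with such a stretch by a narrow margin, although H2-K1 and H2-D1 lie 40.3 and 39.0 Mb away, outside it. The ratio of H2-D1 was 0.566 (0.489 to 0.653) in ductal-like and 0.0996 (upper bound 0.163) in mesenchymal-like cells, the latter from 18 knockout UMIs. A variant that lowers the count by the same factor in every class does not alone account for both. Such a variant beside another difference stays open, as the test cannot tell these apart.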
